A study of Macaca mulatta with 12 samples.

How the data were processed

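Total RNA was extracted from 100 mg of whole testis tissue that had been stored frozen, and biotin-labelled cRNA was made from 1 microg of it, per the labels. The samples came from 12 male rhesus macaques described as healthy that died of unrelated causes. Each animal gave 1 array of the type Affymetrix Human Gene 1.0 ST, designed for human transcripts, so a probe that differs from the macaque sequence can give a low signal.

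The deposited table holds values on a log2 scale, with the base inferred from their range (-0.261 to 9.662) because the sources used here do not state it. Background correction, summarization, normalization and the choice of features by the authors are not given in the sources used here. Array medians lay between 4.118 and 4.286. Sorted values of the other arrays differed from those of the animal of 16 days by up to 0.631, so the features held here do not share a single distribution. Whether arrays were quantile-normalized before features were chosen is not known. No array was a copy of another. The raw image files were not analysed here.

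Of 10936 features, 10019 had 1 gene symbol in the array's annotation of 2016, 250 had several and 667 had none. The 9980 genes with 1 symbol were tested, and for 32 genes with several features the one with the highest mean was used. Chromosomes came from a macaque gene annotation by symbol, for 9791 genes (98.1%), of which 346 are X-linked. For arrays, precision is limited by their number.

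Groups were formed from the age label alone. They were under 3 years (n = 5), 3 to under 5 years (n = 3) and over 6 years (n = 4), with subgroups of 2 neonatal, 3 juvenile, 2 young adult and 2 aged animals. Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adults and immature animals were fitted as 2 groups. Comparisons with the animals of 3 to 4 years came from a fit of 3 groups, and those of subgroups from a fit of 4 subgroups that shares their spread. Testis weight and age in days, each as log2, were fitted together over 12 animals. The position of an animal is its mean over a set of genes as a percentage of the distance from the immature to the adult mean, without a test; immature and adult animals were left out of their own mean.

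The comparisons, gene lists and rule for named genes were fixed before the data were examined. The 26 lists were spermatogonia, meiosis, piRNA pathway, acrosome and sperm surface, spermatid chromatin, sperm flagellum and energy, axoneme and cilium, Sertoli cell, Leydig cell and steroidogenesis, cholesterol synthesis, peritubular and smooth muscle, extracellular matrix, endothelium, macrophage and leukocyte, red blood cell, epididymis, mitotic cell cycle, imprinted growth genes, IGF axis, autosomal retrogenes of X-linked parents, these parents, interferon response, senescence and inflammation, immediate early and heat shock, cytosolic ribosomal proteins and oxidative phosphorylation. All X-linked genes made up 1 more. Lists with at least 3 measured genes, 25 in number, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which called 19, 0, 12, 0 and 0 lists in the 5 group comparisons, taken in the order of the report. No camera call was kept with the estimated correlation. The cytosolic ribosomal list, with 2 measured genes, and the red blood cell list, with 1, were not tested.

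Named genes in the adult and immature comparison were the 12 largest rises and 12 largest falls among called genes without overlap between groups, and up to 4 called members of each list. In each other group comparison they were the 5 largest rises and falls and up to 2 members per list, and for each slope the 3 smallest p values. PRM1, DDX4, MKI67 and COL1A1 were named in each group comparison whatever their result; AMH, INSL3, SYCP3 and STAR, chosen likewise, had no feature with that symbol alone. Where a list had few called genes, its remaining members were named after their values were seen.

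The alternatives tried were quantile normalization, centring of arrays, leaving out the lowest 25% of genes, trend and robust eBayes, array quality weights, the mean over features of a gene, a pseudocount of 16 on the unlogged scale, a minimum log2 change of 1, other choices of animals or slopes in the fit, and leaving out each animal. In data simulated at these group sizes, with 100 genes changed by 1 and 100 by 2 on the log2 scale, the fit of adults and immature animals recovered 68% and 98%, that of 3 to 4 years and immature animals 65% and 97%, that of adults and 3 to 4 years 58% and 94%, that of juveniles and neonates 36% and 90%, and that of aged and young adults 38% and 88%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 read the table, and matplotlib 3.10.9 drew the figures.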

Results

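Gene expression was profiled in the testes of 12 male rhesus macaques that died between 16 days and 26 years of age, 1 animal per array. The title and design text of the series give its subject as the development of the testis after birth. The labels fall into 5 animals under 3 years (16, 20, 215, 471 and 739 days, called immature), 3 animals of 3 to 4 years (3.1, 3.3 and 4.1 years) and 4 animals over 6 years (6.5, 7, 22.2 and 26.1 years, called adult). Testis weight, whose unit the labels leave out, was 0.07 to 0.4 in immature animals and 8.8 to 27.9 in adults. In the animals of 3.1, 3.3 and 4.1 years it was 3.3, 0.6 and 1.2. The free-text description of the animal of 16 days gives an age above 0.1 years, which does not match its title and age label; the label was used. RNA was hybridised to arrays designed for human genes, and 9980 genes were tested. Array medians lay between 4.12 and 4.29 on a log scale whose base is taken as 2, and folds assume that base. The number of arrays limits the precision, and since animals of a group differ in age, the spread within a group includes age.

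The first question was how the adult testis differs from the immature one. Transcripts of meiosis and of sperm formation were far higher in the 4 adults than in the 5 immature animals. The mRNA of PRM1, a protamine that packs sperm DNA, was 47.7-fold higher (log2 change 5.58, SE 0.78), at 7.96 ± 0.22 (SD, n = 4) against 2.38 ± 1.97 (SD, n = 5). It was 82.7-fold higher without the animal of 471 days (immature replicate 4), whose PRM1 value of 5.56 was the highest of the immature group. Of 9980 genes, 2644 were higher and 3008 lower in adults (limma, Benjamini-Hochberg adjusted p under 0.05), which is 56.6% of those tested. Of these, 1506 rose and 1095 fell by at least 1 on the log2 scale. In 4703 genes (47.1%) no adult value overlapped an immature one, where chance gives 1.59%.

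The 12 genes with the largest rises were each at least 37.4-fold higher, with every adult above every immature animal. Besides PRM1 they included the transition proteins TNP1 (log2 change 5.75, SE 1.02) and TNP2 (5.30, SE 0.78), which stand between histones and protamines in spermatid chromatin. CRISP2, a secreted protein of the acrosome, rose by 5.75 and ADAM2, a sperm surface protein, by 5.74. SPZ1, SPATA4, KLHL10, ADAM5, SLC26A8, HORMAD1 and SPDYA completed the set, with log2 changes of 5.69, 5.68, 5.55, 5.52, 5.42, 5.26 and 5.23. The spread of these genes was wide among immature animals, with an SD of 2.59 for TNP1, and the animal of 471 days had the highest immature value of each. Its TNP1 value was 7.41, against 1.00 to 3.65 in the other 4 immature animals and 8.62 to 9.10 in adults, and its ADAM2 value 2.25, against 6.19 to 7.14 in adults. Without it the rise of TNP1 was 113-fold, of CRISP2 96.6-fold, of SPZ1 85.0-fold, of SPATA4 78.9-fold, of TNP2 72.0-fold, of ADAM5 71.0-fold, of HORMAD1 63.9-fold and of SPDYA 57.5-fold. Immature values of several of these genes lay near the lower end of the arrays, as for SPATA4 at -0.09 to 0.89 in 4 animals where the lowest value of any array was -0.261. No background was measured, so the size of such folds is uncertain.

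Most genes of the germ-cell lists from meiosis onward rose. Of 23 measured genes of meiosis, 22 rose, with a median log2 change of 2.34; HORMAD2 rose by 4.49, HSPA2 by 4.41 and SYCE2, part of the synaptonemal complex, by 3.35. Of 14 genes of the piRNA pathway, which silences transposons in germ cells, 13 rose (median 2.21), with PIWIL1 up by 3.41, GTSF1 by 3.20, TDRD5 by 2.81 and RNF17 by 2.77. The acrosome and sperm surface list had 13 of 14 genes higher (median 3.82), among them LYZL6 (4.69) and SPATA16 (4.31). All 19 genes of the sperm flagellum and its energy supply rose (median 3.85), with FSCN3 at 5.21, OAZ3 at 5.13 (5.73 without the animal of 471 days) and the sperm glycolytic enzyme GAPDHS at 4.96. All 22 axoneme genes rose (median 3.33), led by SPAG17 (4.94), SPAG6 (4.70), TEKT2 (4.50) and ODAD2 (3.82). In spermatid chromatin 6 of 7 genes rose (median 1.56), with the linker histone H1-7 at 1.56. Camera adjusted p was 1.71e-10 for meiosis, 1.39e-06 for piRNA, 7.21e-08 for acrosome, 4.35e-11 for flagellum, 2.69e-13 for axoneme and 0.00753 for spermatid chromatin. With an estimated correlation between genes the adjusted p of these lists lay between 0.402 and 0.409. Adjusted over the list alone, the counts were 22, 14, 13, 19, 22 and 6. In these lists, as in the other 7 that camera called in this comparison, the mean of every adult lay beyond that of every immature animal.

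Spermatogonial genes were mixed. Of 14 measured, 4 rose and 1 fell, with MORC1 (2.24), the germ-cell helicase DDX4 (2.15), DAZL (1.84) and DMRT1 (0.79) higher and GFRA1, the receptor of the stem-cell factor GDNF, lower (log2 change -1.17, SE 0.20); adjusted over the list alone the counts were also 4 and 1. Camera did not call this list (median 0.21, adjusted p = 0.309). Of 22 genes of the mitotic cell cycle, 16 rose and MCM3 fell by 0.52 (median 0.92, camera adjusted p = 4.72e-05, and adjusted p = 0.415 with an estimated correlation; 16 and 1 over the list alone). CCNB2 rose by 3.72, FOXM1 by 2.89, BUB1 by 2.57 and PLK1 by 2.28; the proliferation marker MKI67 did not pass (log2 change 0.62, SE 0.34, adjusted p = 0.145) except without the animal of 20 days (0.86, adjusted p = 0.027).

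The largest falls were in genes of other kinds. LIPH, a lipase that makes lysophosphatidic acid, was 17.4-fold lower (log2 change -4.12, SE 0.15), and the amino acid transporter SLC38A1 16.5-fold lower. The desmosome genes DSC2 and DSP had log2 changes of -3.90 and -3.62, the endothelin receptor EDNRB -3.61, the nitric oxide receptor subunit GUCY1A1 -3.59, and GNRHR, the receptor of gonadotropin-releasing hormone, -3.47. Adult values of GNRHR, 0.14 to 0.57, lay near the lowest value of any array, -0.261, so the size of its fall is uncertain. NRK (-3.60), FHDC1 (-3.50), GPC3 (-3.43), EDIL3 (-3.39) and ERBB3 (-3.31) made up the rest of the 12.

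Genes of the extracellular matrix fell together. Equal amounts of RNA from whole testis were compared, so these and the other changes are in share of that RNA. Change per cell was not measured. Of 27 measured, 20 were lower and none higher (median log2 change -1.35), with COL1A1 at -2.66 (SE 0.47), POSTN at -2.46 (-1.84 and not called without the animal of 16 days, adjusted p = 0.0621, and -3.04 without that of 471 days), COL3A1 at -2.21 and COL15A1 at -2.08. Camera adjusted p was 1.96e-05, and adjusted p = 0.531 with an estimated correlation; 21 fell adjusted over the list alone. In the IGF axis 6 of 13 genes fell, including IGFBP3 (-2.36), IGFBP5 (-2.30), the growth hormone receptor GHR (-2.11) and INSR (-1.11), with a median of -0.70, camera adjusted p = 0.0221 and adjusted p = 0.402 with an estimated correlation. Of 8 imprinted growth genes 5 fell, PLAGL1 (-2.83), DLK1 (-1.54), SGCE (-1.40), DCN (-0.86) and NDN (-0.68), and GRB10 rose by 0.61 (median -0.77, camera adjusted p = 0.0369, and adjusted p = 0.428 with an estimated correlation). Of 11 interferon response genes 9 fell, among them the RNA sensor RIGI (-2.12), MX1 (-1.82), XAF1 (-1.58) and IFIT2 (-1.53), with a median of -1.12, camera adjusted p = 0.00236 and adjusted p = 0.409 with an estimated correlation. Adjusted over the list alone, 6, 6 and 10 genes of the IGF, imprinted and interferon lists passed. Without the animal of 16 days the imprinted list was no longer called (camera adjusted p = 0.0534).

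Of 346 X-linked genes 199 fell and 37 rose, with a median log2 change of -0.67. Camera adjusted p was 7.21e-08, and adjusted p = 0.409 with an estimated correlation; adjusted over the list alone 208 fell and 38 rose. The X-linked flagellum gene AKAP4 rose by 3.80 and CXorf65 by 3.41. Among 9445 autosomal genes 29.3% fell and 26.9% rose, against 57.5% and 10.7% on the X chromosome. Of 4 autosomal retrogenes copied from X-linked parents 2 rose, PDHA2 by 4.18 and RBMXL2 by 2.58 (median 1.43, camera adjusted p = 0.0456, and adjusted p = 0.468 with an estimated correlation). Without the animal of 16 days, 20 days or 6.5 years camera adjusted p for this list was 0.0539, 0.056 or 0.0697. Of their 6 measured X-linked parents 4 fell, TAF1 (-0.93), PRPS1 (-0.88), UTP14A (-0.80) and PDHA1 (-0.53), and 2 rose, NXT2 (0.62) and CSTF2 (0.48); camera did not call this list (median -0.66, adjusted p = 0.466).

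**Figure D1:**
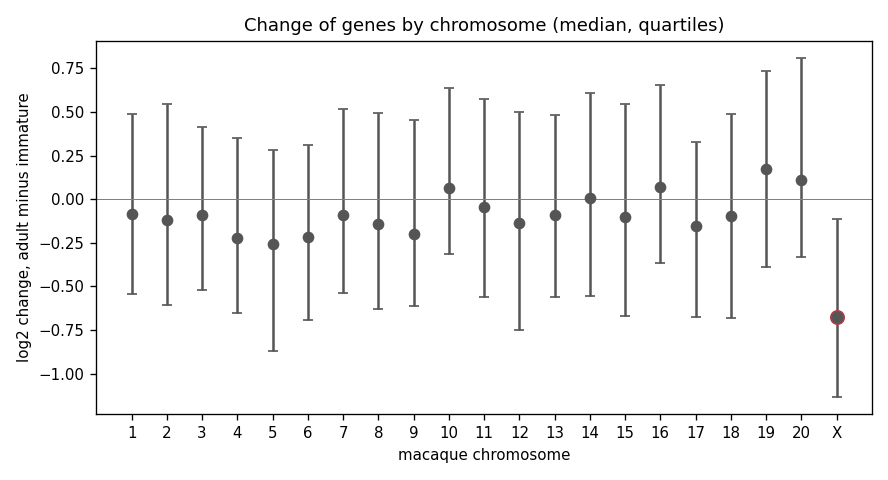
Log2 change between adult (n = 4) and immature (n = 5) testis for the genes of each macaque chromosome, as the median (point) with quartiles (bars); the point of the X chromosome is outlined in red. The X-linked median is -0.67, below the median of each autosome, which lie between -0.26 and 0.17.

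Markers of the somatic cells of the testis, likewise measured as a share of whole-testis RNA, moved less evenly. Of 14 Sertoli cell genes 6 fell, including the AMH receptor AMHR2 (-3.10, SE 0.45), INHBB (-1.46) and GATA4 (-1.24), while the tight junction gene CLDN11 rose by 1.59. Of 11 Leydig cell genes 4 fell, among them DLK1 (-1.54), SCARB1 (-1.05), NR5A1 (mean 3.55 against 4.55) and GSTA3 (-0.55). Endothelial genes had 6 of 10 lower, with KDR at -1.42, PECAM1 at -0.77, TEK at -0.76 and ERG at -0.70. Peritubular and smooth muscle genes went both ways, with 5 of 14 lower, SYNPO2 (-1.64), TPM2 (-0.96), CALD1 (-0.86), LMOD1 (-0.74) and PTCH1 (-0.67), and 2 higher, ACTG2 (1.55) and ACTA2 (1.07). Camera adjusted p for these 4 lists was 0.132, 0.218, 0.0586 and 0.701, with medians of -0.61, -0.55, -0.56 and -0.22. The Sertoli cell list was called without the animal of 7 years (adjusted p = 0.045), and the endothelial list without that of 215 days, 471 days, 739 days or 6.5 years (adjusted p = 0.039, 0.0462, 0.0331 or 0.0353). In the macrophage and leukocyte list CD163 rose by 1.41 and PTPRC had a log2 change of -0.82, and the other 7 genes did not pass. The only measured red blood cell gene, AHSP, rose by 2.27. Of 3 epididymis genes DEFB123 rose by 2.24; the median of the 3 was -0.14 and their mean 0.61. Cholesterol synthesis had 4 of 12 genes lower, SC5D (-0.96), TM7SF2 (-0.86), MSMO1 (-0.78) and NSDHL (-0.70), and MVD higher (0.59). In the lists of senescence and inflammation, immediate early and heat shock genes, and oxidative phosphorylation the numbers higher and lower were 1 and 1 of 5, 0 and 2 of 8, and 3 and 2 of 6. They were CDKN1A (0.86) and IGFBP3 (-2.36), then JUN (-1.65) and KLF6 (-0.70), then NDUFV1 (0.91), NDUFS3 (0.84), UQCRC1 (0.55), NDUFS1 (-0.37) and ATP5F1C (-0.34). Camera called none of these lists, nor macrophage, epididymis or cholesterol synthesis. Neither of 2 measured cytosolic ribosomal protein genes passed. No alternative moved the adult counts by over 1.5 times except the minimum change and a slope on age in place of the groups, which called 1793 genes lower.

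**Figure D2:**
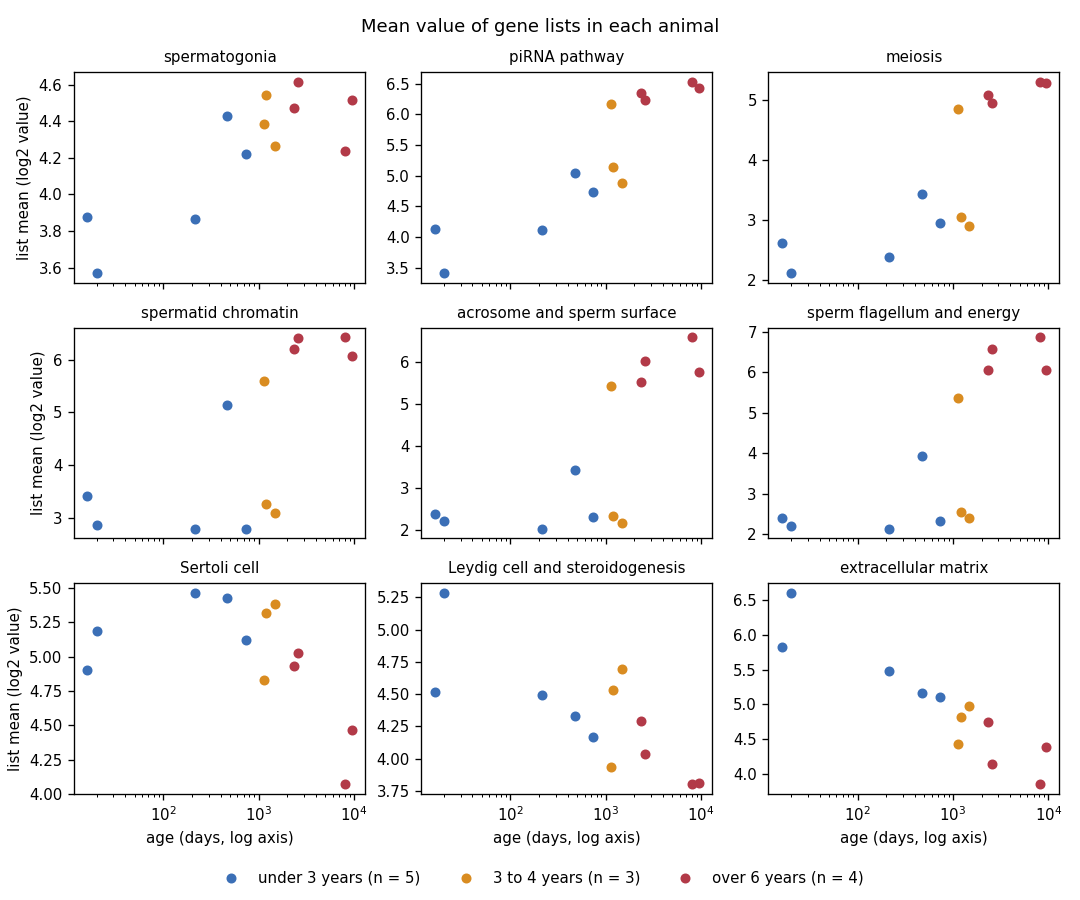
Mean log2 value of 9 gene lists in each of the 12 animals against age in days on a log axis, coloured by age group. In the lists of spermatid chromatin, acrosome and flagellum the animals of 3.3 and 4.1 years lie with the immature animals, and those of 3.1 years and, less far, 471 days lie toward the adults.

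The animals of 3 to 4 years were described singly, as a share of the distance from the immature mean to the adult mean. On the genes that rose in adults, the animal of 3.1 years lay at 69.8%, that of 3.3 years at 9.2% and that of 4.1 years at 4.2%. On the genes that fell these positions were 68.5%, 11.5% and 12.2%. Immature animals had an SD of 14.1 percentage points on the genes that rose and 10.9 on those that fell, and adults 18.0 and 16.3. The animals of 3.3 and 4.1 years therefore lay within about 1 SD of the immature mean on the genes that rose. On both of these gene sets the animal of 3.1 years lay outside the range of either group. The genes were chosen for their difference between these same immature and adult animals, which by itself holds the 2 groups apart. In that animal, genes of meiosis stood at 87.7%, of the piRNA pathway at 89.3%, of spermatid chromatin at 76.1% and of the flagellum at 72.8%. In the animals of 3.3 and 4.1 years the piRNA list stood at 40.8% and 28.4% and meiosis at 14.3% and 8.5%, while spermatid chromatin stood at -4.5% and -10.5%. Extracellular matrix genes stood at 60.2% and 48.6%. Immature animals had an SD of 38.6 points on the piRNA list, 40.0 on spermatid chromatin and 62.7 on the matrix list, with highest values of 41.7%, 65.5% and 44.8%; on meiosis the highest was 34.8%. On the piRNA and meiosis lists the animals of 3.3 and 4.1 years thus lay within the immature range. The upper end of that range was the animal of 471 days on both lists, and the next immature values were 25.1% and 12.2%, at 739 days. Both animals lay above the next value on the piRNA list, and on meiosis only that of 3.3 years did. The immature animal of 471 days stood at 24.1% on the genes that rose, where the other 4 immature animals ran from -10.2% to -0.7%.

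**Figure D3:**
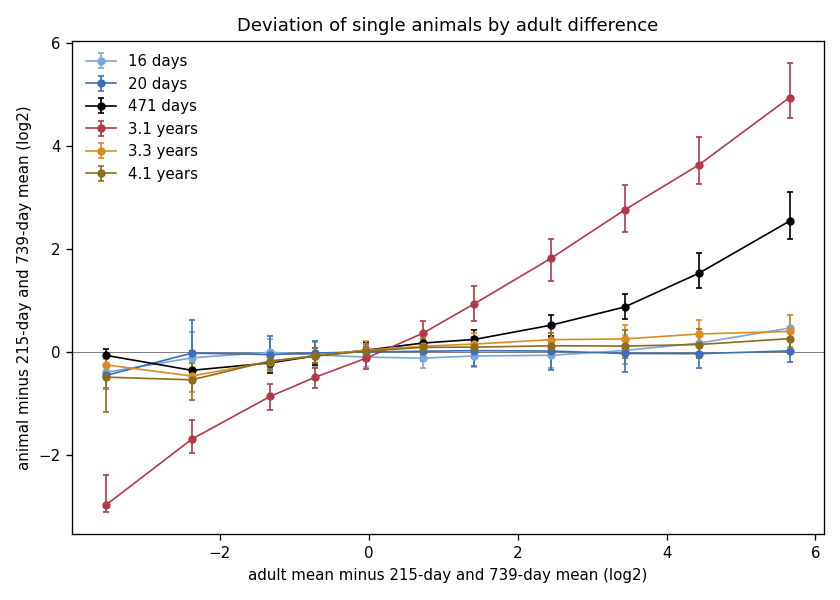
Median deviation (points, with quartiles as bars) from the mean of the animals of 215 and 739 days in 6 animals, on the log2 scale, for genes binned by the difference between the adult mean and that mean. The animal of 471 days departs upward in genes that are much higher in adults, less than the animal of 3.1 years does.

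**Figure D4:**
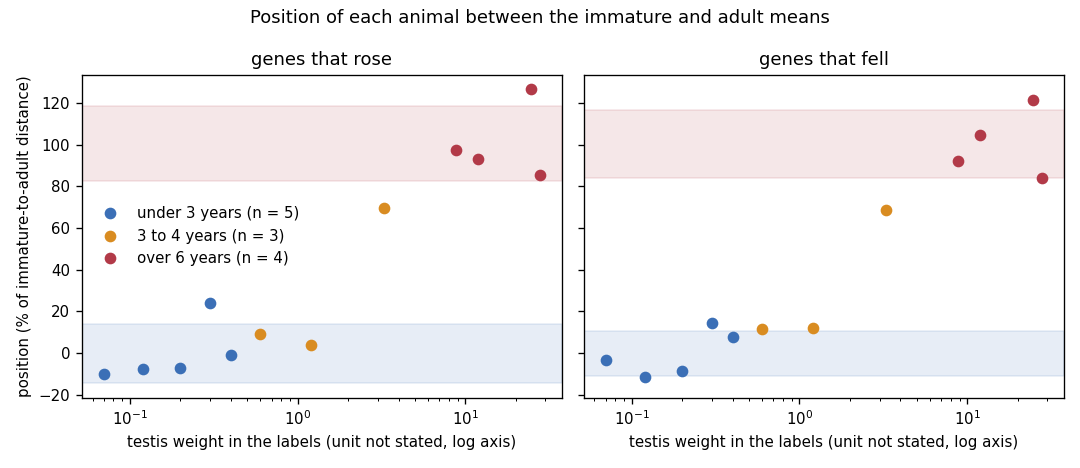
Position of each animal between the immature mean (0%) and the adult mean (100%) on the genes that rose and fell in adults, against testis weight on a log axis; immature and adult animals are set against a mean that leaves them out. Bands show the mean ± SD of immature (n = 5) and adult (n = 4) animals, and the animal of 3.1 years lies between them at 69.8% and 68.5%.

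As a group, the 3 animals of 3 to 4 years were set against the immature animals. Limma called 0 genes higher and 0 lower, with a lowest adjusted p of 0.0502, and 1244 genes had an unadjusted p under 0.05; with array quality weights it called 29 higher and 39 lower. DDX4 stood at 6.94 ± 0.94 (SD, n = 3) against 5.77 ± 0.76 (SD, n = 5) and PRM1 at 3.55 ± 2.81 against 2.38 ± 1.97. The PRM1 log2 change of 1.17 turned to -0.45 without the animal of 3.1 years, and was 1.90, 2.05 or 1.96 without that of 3.3 years, 4.1 years or 471 days. COL1A1 stood at 5.19 ± 0.69 against 6.67 ± 0.79, and MKI67 at 3.36 ± 0.60 against 3.70 ± 0.76. As lists, camera called the spermatogonia, meiosis, piRNA, acrosome, flagellum and axoneme genes higher, and extracellular matrix, endothelium, peritubular, imprinted and X-linked genes lower. The lowest of these were the matrix list (median log2 change -0.93, camera adjusted p = 3.74e-12) and the piRNA list (median 1.20, camera adjusted p = 6.31e-11). With an estimated correlation the adjusted p of the called lists lay between 0.566 and 0.583. Without the animal of 3.1 years, the acrosome list had a median log2 change of -0.28 and the flagellum list -0.06, and neither these nor the axoneme, imprinted and X-linked lists were called. Without the animal of 3.3 years the spermatogonia list was not called (camera adjusted p = 0.0755), nor the imprinted list without that of 16 days (0.0529), and limma called 1 gene higher and 4 lower. Other lists gained a call. Spermatid chromatin was called higher without the animal of 471 days, 3.3 years or 4.1 years (camera adjusted p = 0.0123, 0.0381 or 0.0321), and the mitotic list without that of 20 days, 3.3 years or 4.1 years (0.00328, 0.00214 or 0.0163) and at 0.05 after quantile normalization. Interferon genes were called lower without the animal of 20 days or 3.3 years (0.00742 or 0.00617), and cholesterol synthesis without that of 16 or 215 days (0.0294 or 0.0261). Limma called 2 genes higher without the animal of 22.2 years and 1 lower without that of 471 days or of 3.1 years.

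Adults against the animals of 3 to 4 years gave 1720 genes higher and 1646 lower. TNP1 was 26.3-fold higher in adults (log2 change 4.72, SE 1.52), FSCN3 24.0-fold, SPZ1 21.8-fold, PRM1 21.2-fold and CRISP2 19.6-fold. These means of 3 animals hold the animal of 3.1 years, whose TNP1 value was 8.14 against 2.30 and 2.06 in those of 3.3 and 4.1 years. Without it the folds were 104, 65.8, 81.4, 65.4 and 78.3. TNP1 stood at 13.8-fold or 12.7-fold without the animal of 3.3 or of 4.1 years and was not called (adjusted p = 0.143 or 0.149), nor were SPZ1 (13.2-fold or 9.67-fold), PRM1 (12.7-fold or 11.5-fold) and CRISP2 (10.8-fold or 8.85-fold); FSCN3 stood at 14.4-fold or 14.7-fold and was called. LIPH (log2 change -3.03), AMHR2 (-2.99), GUCY1A1 (-2.82), SLC38A1 (-2.82) and DSP (-2.64) had the largest falls; without the animal of 3.1 years LIPH stood at -3.97, GUCY1A1 at -3.68, SLC38A1 at -3.77 and DSP at -3.67. DDX4 (0.98), MKI67 (0.95) and COL1A1 (-1.19) did not pass (adjusted p = 0.107, 0.0898 and 0.109), but did without the animal of 3.1 years (0.0105, 0.0261 and 0.0464) and with array quality weights (0.00172, 0.00769 and 0.00155), and COL1A1 without that of 6.5 years (0.0331). All 22 axoneme genes, 18 of 19 flagellum genes, 16 of 23 meiosis genes, 12 of 14 acrosome genes, 10 of 22 cell cycle genes and 5 of 14 piRNA genes rose. Adjusted over the list alone these counts were 22, 19, 18, 13, 11 and 9. Among the X-linked genes 133 of 346 fell and 18 rose, 7 of 11 interferon genes fell and 5 of 13 IGF axis genes fell, with IGF1 at -1.27. The spermatogonial genes PIWIL4 (-1.32) and TSPAN33 (-0.63) fell, and the smooth muscle genes ACTG2 (1.64), ACTA2 (1.26), TAGLN (1.04) and DES (0.75) rose. Camera called 8 lists higher and 4 lower, and the adjusted p of these lay between 0.434 and 0.771 with an estimated correlation. The matrix call (median -0.40, camera adjusted p = 0.0413) was lost after quantile normalization (0.0592) and without the animal of 4.1, 7 or 22.2 years (0.0965, 0.0746 and 0.174), and stood at 0.05 without that of 26.1 years. The Sertoli cell list gained a call as lower without the adult of 6.5 or of 7 years (0.0139 or 0.0147). The counts of genes rested on the animals of 3.3 and 4.1 years. Without the first they were 499 and 364, and without the second 449 and 312; without the adult of 22.2 years the number lower was 1049.

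Within the immature group, the 3 juveniles (215 to 739 days) were set against the 2 neonates (16 and 20 days). Matrix transcripts led the falls, with POSTN 12.2-fold lower in juveniles (log2 change -3.61, SE 0.58) and VCAN 7.68-fold lower, at 3.46 ± 0.57 (SD, n = 3) against 6.40 ± 0.57 (SD, n = 2). ASPN (-2.72), SLITRK6 (-2.23) and the fatty acid transporter CD36 (-2.16) followed. POSTN stood at -4.39 without the animal of 215 days, ASPN at -1.75 and not called without that of 20 days and at -3.69 without that of 16 days. SLITRK6 (-1.60) and CD36 (-1.45) were not called without the animal of 16 days, and stood at -2.85 and -2.87 without that of 20 days. PRM1 (0.56), DDX4 (0.72), MKI67 (-0.50) and COL1A1 (-0.99) did not pass (adjusted p = 0.909, 0.54, 0.758 and 0.506). Leaving out 1 animal put PRM1 between -0.91 (471 days) and 1.59 (16 days), MKI67 between -1.19 (16 days) and 0.19 (20 days), and COL1A1 between -1.69 (16 days) and -0.29 (20 days). The fetal growth regulators IGF2BP3 (-1.53) and IGF2BP2 (-1.32), the macrophage receptor CD163 (-1.45), the luteinizing hormone receptor LHCGR (-1.31) and the X-linked TENM1 (-2.01) and GPC3 (-1.81) also fell. USP44 (1.98), SEMA3D (1.85), STK33 (1.80), the adhesion gene CDH1 (1.77) and the mast cell protease CPA3 (1.44) were the largest of 7 rises. In all, 7 genes were higher and 53 lower, with 1138 genes at an unadjusted p under 0.05. Camera called 6 lists higher, led by piRNA (median 0.81, adjusted p = 1.66e-08), and 8 lower, led by the matrix (median -0.90, adjusted p = 6.24e-16); with an estimated correlation their adjusted p lay between 0.384 and 0.663. The counts moved to 0 and 5 without the animal of 20 days, 24 and 67 without that of 215 days, 3 and 17 without that of 16 days, 2 and 11 without that of 739 days, and 3 and 11 without the adult of 6.5 or of 7 years, and the number lower was 16 without the animal of 471 days. Limma on the 5 immature animals alone called 0 of the 60 genes, and without the animal of 20 days the meiosis, spermatogonia, interferon, Leydig, peritubular, macrophage, axoneme, flagellum and mitotic lists were no longer called. Nor were the macrophage and mitotic lists without the animal of 215 days (camera adjusted p = 0.0946 and 0.544), the axoneme and flagellum lists without that of 471 days (0.484 and 0.541), or the interferon list without that of 739 days (0.0568). Calls were gained by the Sertoli cell list after quantile normalization (0.034) and without the animal of 739 days (0.0127) or the adult of 6.5 or of 7 years (0.0242 each). The acrosome and cholesterol lists gained one without the animal of 215 days (0.0162 and 0.0222), and the immediate early list without that of 20 days (0.0419).

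Between the 2 aged adults (22.2 and 26.1 years) and the 2 young adults (6.5 and 7 years) limma called 0 genes in each direction, with a lowest adjusted p of 0.174 and 1322 genes at an unadjusted p under 0.05. PRM1 stood at 7.95 ± 0.18 in aged and 7.97 ± 0.34 in young adults (SD, n = 2 each), and DDX4 at 8.06 ± 0.08 and 7.78 ± 0.08. MKI67 stood at 4.44 ± 0.53 and 4.19 ± 0.23, and COL1A1 at 3.45 ± 0.70 and 4.56 ± 1.09, a log2 change of -1.11 that was -0.34 without the animal of 6.5 years and -1.89 without that of 7 years. Testes weighed 24.6 and 27.9 in aged and 11.9 and 8.8 in young adults, and the animal of 22.2 years stood at 126% on the genes that rose and 121% on those that fell, with a Sertoli cell list mean of 4.07, so age is not separated from weight here. The mean of the Sertoli cell list was 4.27 ± 0.28 in aged and 4.98 ± 0.07 in young adults, with each of its 14 genes lower in aged animals (median log2 change -0.80, camera adjusted p = 1.29e-05, and adjusted p = 0.624 with an estimated correlation). Adjusted over the list alone, 6 of the 14 passed. CLDN11 (log2 change -1.15, SE 0.31), GATA4 (-1.07), WT1 (-0.95) and SOX9 (-0.92), named after their values were seen, had unadjusted p of 0.00328, 0.00554, 0.00401 and 0.0101. Camera also called the senescence, matrix and peritubular lists lower and the meiosis list higher, with adjusted p between 0.0302 and 0.0319 and, with an estimated correlation, between 0.624 and 0.834. The matrix, peritubular and senescence lists were not called without the animal of 6.5 years (camera adjusted p = 0.888, 0.881 and 0.134) or of 22.2 years (0.701, 0.614 and 0.127), nor meiosis without that of 7, 22.2 or 26.1 years (0.223, 0.106 and 0.079). Calls were gained without the animal of 26.1 years by acrosome, flagellum and axoneme as higher (0.00219, 0.0308 and 0.00247) and by the IGF axis and X-linked genes as lower (0.0391 and 0.00123), and by acrosome without that of 7 years (0.0497). In simulated data of this size 38% of genes changed by 1 and 88% of genes changed by 2 on the log2 scale were recovered.

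Testis weight and age were then fitted together over the 12 animals, each on a log2 scale. Per doubling of weight at a given age, 1902 genes were higher and 2331 lower. The smallest p values belonged to XAF1 (slope -0.61, SE 0.04), DSP (-1.03, SE 0.08) and GUCY1A1 (-0.97, SE 0.08). Per doubling of age at a given weight, 161 genes were higher and 80 lower, led by XAF1 (slope 0.45, SE 0.04) and the ion channel genes KCNH1 (0.62, SE 0.07) and GRIK3 (0.52, SE 0.06). Of these 241 genes 223 were also called for weight, each with the opposite sign. Log2 age and log2 weight correlated at 0.898, so errors of the 2 slopes run against each other and opposite signs can follow from that. XAF1 stood at 3.78 to 5.26 in immature animals and at 2.95 to 3.28 in adults, so its positive age slope holds only at a given weight. Weight and age rise together in these animals, so the fit separates them mainly through animals whose weight and age are out of step. The age counts fell to 37 and 6 without the animal of 20 days, 34 and 23 without that of 16 days, 63 and 35 without that of 739 days, 22 and 10 without that of 3.3 years, and 62 and 39 without that of 4.1 years. Without the animal of 215 days 53 genes were lower, and without that of 471 days 206 were.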

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

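All tests weighed in this part were chosen only after the result was seen, and the yardstick for the mixture test of the animal of 3.1 years was set after its value was first seen. In groups of 4 or 5 animals, 310 sets of values were examined for a single animal far from the others, by the gap to the nearest animal over the range of the group. This ratio was above the critical value in 36, where chance alone gives about 15.5; the sets are not independent of one another. Of the 36, 20 belong to the immature animal of 471 days.

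The animal of 471 days was the highest of 5 immature animals in the lists of acrosome (ratio 0.745), spermatid chromatin (0.733), flagellum (0.853), axoneme (0.73) and retrogenes (0.806). It was also highest for CRISP2 (0.717), SPATA4 (0.72), KLHL10 (0.817), TNP2 (0.88), SPDYA (0.717), SPATA16 (0.771), FSCN3 (0.793), OAZ3 (0.862), GAPDHS (0.751), SPAG6 (0.744), TEKT2 (0.816), PDHA2 (0.827), RBMXL2 (0.872) and AKAP4 (0.723). Its position on the genes that rose in adults, 24.1% against a next value of -0.7%, had a ratio of 0.724.

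For the animal of 471 days, an adult array carrying this label is argued against by its lowest correlation with the other immature arrays, 0.917 over the 9980 genes tested, which exceeds its highest with an adult array, 0.822. Its correlations with the arrays of 3.3 and 4.1 years, 0.962 and 0.958, exceeded its highest with another immature array, 0.954, and that with 3.1 years was 0.869. Over all features the array of 739 days also correlated more with those of 3.3 and 4.1 years (0.975 and 0.977) than with any immature array (highest 0.970). Other wrong labels were not tested. The labelled testis weight of 0.3 lies between 0.2 at 215 days and 0.4 at 739 days, below the 0.6 to 3.3 of 3 to 4 years. An early first wave of spermatogenesis with early stages first stays open, since the lists differed. Spermatid chromatin stood 30.7 points above meiosis, beyond the SD of 21.8 among the other 4 immature animals, which goes against it. Flagellum stood at 5.71 and acrosome at -2.70 points, within SDs of 16.4 and 16.6. The unlogged shares, 16.8% for piRNA, 12.2% for meiosis and 10.9% for spermatid genes, fell in the order of stages. The animals of 3.3 and 4.1 years, by contrast, had all 3 spermatid lists below meiosis, with spermatid chromatin at -18.9 and -19.0 points. RNA of adult testis mixed into the sample stays open too. On the unlogged scale, taking base 2, the median adult share of 34 spermatid genes over that of 15 meiosis genes was 0.896. Its 95% bootstrap interval, 0.621 to 1.32, resamples genes of this 1 array and leaves out variation between animals. At 3.3 and 4.1 years the ratio was 0.101 (0.0364 to 0.337) and 0.151 (-0.00299 to 0.743). A few tubules with complete spermatogenesis would give the same ratio, 0.896, so the test does not separate it from mixed RNA, and age and individual development stay untested. The share was 9.49% over 659 genes; a mixture curve with a free log base gave 14.9% at base 1.57 with the animals of 215 and 739 days as reference, and 9.19% at base 1.97 with those of 3.3 and 4.1 years added, so the base is not settled by it.

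The animal of 3.1 years lay near the adults, and 3 explanations were weighed. Taking base 2, the genes that fall most argue against a mixture of immature and adult RNA at the median share of rising genes. That share over 659 genes was 59.6% (quartiles 40.6% and 79.9%), at which the immature RNA left would keep log2 changes above -2. Shares of 79.1% for meiosis and 82.2% for piRNA genes would allow changes below -2. The adult array of 6.5 years, set against the other adults, itself read only 74.6%. A mixture at a larger share is therefore left open. Deviations were taken from the mean of the animals of 215 and 739 days. Their median was -2.96 (quartiles -3.10 and -2.39) in 21 genes with adult differences of -5 to -3. In 113 genes at -3 to -2 it was -1.69 (-1.96 and -1.33), and smaller falls separate less. The ratio of spermatid to meiosis share, 0.592 (95% bootstrap interval 0.457 to 0.879), lies below the 4 adult arrays (0.732 to 1.49). Its interval, which resamples genes of this 1 array, reaches their range, so the ratio does not decide. A mixture at a larger share and the other explanations cannot be told apart with 1 animal. An adult array under this label is left open because the position on the genes that rose was -1.72 adult SDs from the adult mean, and on those that fell -1.96, while the labelled testis weight of 3.3, below the adult 8.8 to 27.9, speaks against a wrong age but not against an exchanged array. Further puberty is left open because the heaviest testis of the 3, at 3.3, had the highest position, 69.8%. On the genes that rose the animals with weights of 0.6 and 1.2, at 9.2% and 4.2%, were not in that order. On the genes that fell, at 11.5% and 12.2%, they were. Both gaps are smaller than the immature SDs of 14.1 and 10.9 points.

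The X-linked genes had a median log2 change of -0.672 between adult and immature testis. Dilution of the transcripts of the immature testis by germ-cell RNA, acting alike on X-linked and autosomal genes, is argued against by 10000 lists of autosomal genes. They were matched on their level in immature testis, and their medians centred on -0.0616 (95% between -0.154 and 0.0322, lowest -0.243). The arrays of 16 and 471 days as the cause are argued against by the difference between X-linked and autosomal medians, which was -0.597 without them and -0.600 with them. It stays open whether X-linked genes hold fewer genes expressed in germ cells. The lists were not matched on that, so dilution of the X-linked genes that fell is not argued against. Silencing of the X chromosome in meiosis was not tested.

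The animal of 16 days was the highest immature animal in the immediate early and heat shock list (ratio 0.711) and for IFIT2 (0.72) and JUN (0.775, at 6.24 against a next value of 4.71). Among the 4 adults, the animal of 6.5 years was highest in the endothelium list (0.904) and for COL15A1 (0.868). The animal of 7 years was highest for AMHR2 (0.956, at 4.67 against a next value of 2.43) and in the epididymis list (0.941, over a range of list means that runs only from 3.38 to 3.39), and lowest for CDH1 (0.878). The animal of 22.2 years was highest for SLC26A8 (0.866) and STK33 (0.947), and lowest for GUCY1A1 (0.925), NSDHL (0.862), SYNPO2 (0.838) and IFIT2 (0.887). The animal of 26.1 years was highest for CPA3 (0.925) and VCAN (0.863, at 4.67 against a next value of 2.93).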

How the results depend on the processing

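The alternatives that left out the animals of 16 and 471 days, or of 3.1 years and 471 days, together were added after the data were seen; the animal of 16 days was chosen for PRM1 and TNP1 values of 3.07 and 3.65, the highest of the immature group after those of 471 days. Of the list results under all alternatives 1489 kept direction and call, 31 gained a call, 90 lost one and 40 reversed; of the named gene results 3532, 8, 334 and 9 did. The 5652 genes called between adults and immature animals included 5020 to 5361 that were called with the same sign without any 1 animal, 5440 after quantile normalization and 4992 without the animals of 16 and 471 days. Positions of the animals of 3 to 4 years moved by less than 1 SD under each alternative tried. No paired analysis was possible because the replicate numbers follow the order of the samples and pair no animals.

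With a minimum change of 1, genes higher and lower were 1506 and 1095 for adults against immature animals, 1042 and 480 for adults against 3 to 4 years, 72 and 2 for the weight slope, and 0 and 0 for the age slope; fewer genes can pass by construction. For the changes that follow, the cause was not tested. A slope on log2 age in place of groups gave 1793 lower. For 3 to 4 years against immature animals, quantile normalization gave 2 and 2, trend and robust eBayes 1 and 1, array weights 29 and 39, and the pseudocount 1 lower. Array weights gave 2688 and 3295 for adults against 3 to 4 years and 480 and 365 for the age slope. For juveniles against neonates trend and robust eBayes gave 11 higher, the pseudocount 2 higher, the compared animals alone 0 and 0, and leaving out the animals of 16 and 471 days 0 and 5. For the age slope the pseudocount gave 252 higher, that same omission 33 and 35, and leaving out the animals of 3.1 years and 471 days 220 lower.

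Leaving out 1 animal at a time, genes higher and lower ranged over 2415 to 2643 and 2662 to 2914 for adults against immature animals, 0 to 2 and 0 to 4 for 3 to 4 years against immature animals, 449 to 2048 and 312 to 2404 for adults against 3 to 4 years, 0 to 24 and 5 to 67 for juveniles against neonates, 1602 to 1981 and 1677 to 2420 for the weight slope, and 22 to 211 and 6 to 206 for the age slope; aged against young adults stayed at 0. Where 1 animal was left in a subgroup, it was assumed to vary like the others. For 3 to 4 years against immature animals the median of the acrosome list ranged from -0.28 to 1.64 and that of the flagellum list from -0.059 to 1.37, both lowest without the animal of 3.1 years. For juveniles against neonates the flagellum list ranged from -0.13 (without the animal of 471 days) to 0.93 and the mitotic list from -0.43 to 0.041 (without that of 20 days).

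Further results whose direction turned without 1 animal, none of them called with all animals, had these ranges over the animals left out; the direction of a list is that of camera and its value a median. For 3 to 4 years against immature animals they were PRM1 -0.45 to 2.05, spermatid chromatin -0.057 to 0.51, Sertoli -0.10 to 0.15, Leydig -0.42 to 0.030, macrophage -0.10 to 0.12, mitotic -0.084 to 0.34, retrogenes -0.032 to 0.41 and interferon -0.59 to 0.11. For adults against 3 to 4 years: spermatogonia 0.0058 to 0.25, peritubular -0.26 to 0.11 and immediate early -0.19 to 0.064. For juveniles against neonates: PRM1 -0.91 to 1.59, MKI67 -1.19 to 0.19, acrosome -0.11 to 0.50, spermatid chromatin -0.16 to 0.67, epididymis -0.076 to 0.13, retrogene parents 0.028 to 0.11, senescence -0.41 to 0.26 and oxidative phosphorylation -0.068 to 0.27. For aged against young adults: PRM1 -0.26 to 0.22, MKI67 -0.12 to 0.63, spermatid chromatin -0.24 to 0.22, flagellum -0.29 to 0.41, axoneme -0.15 to 0.49, cholesterol synthesis -0.31 to 0.014, endothelium -0.29 to -0.055, retrogene parents -0.17 to 0.28, interferon -0.077 to 0.39 and X-linked -0.30 to 0.10. Quantile normalization turned PRM1 (0.016, and 0.0012 by centring) and the epididymis list (-0.091) for aged against young adults, the senescence list (-0.085) for juveniles against neonates and the Sertoli list (-0.011) for 3 to 4 years against immature animals.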

Other observations

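The tests of other splits and of the source array were set before their results were seen; the genes whose values per animal follow were picked after they were seen. GNRHR, the receptor of gonadotropin-releasing hormone, stood at 3.66 to 3.93 in the 5 immature animals, at 2.46 and 1.65 at 3.3 and 4.1 years, at 0.41 at 3.1 years and at 0.14 to 0.57 in the 4 adults. LIPH stood at 6.77 and 6.53 at 3.3 and 4.1 years, within the immature range of 6.52 to 7.10, and DSP at 5.32 and 5.15, within that of 4.68 to 5.52. LHCGR, the luteinizing hormone receptor, stood at 4.24 and 4.47 in the neonates, 2.92 to 3.11 in the juveniles, 3.59, 3.71 and 3.65 at 3.1, 3.3 and 4.1 years, and 3.17 to 4.20 in adults.

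Among germ-cell genes, PIWIL1 stood at 4.63 and 4.31 at 3.3 and 4.1 years, between the immature animals without that of 471 days (3.64 to 4.23) and the adults (7.37 to 7.77), and PRM1 at 2.08 and 1.78, within the immature range. The red blood cell gene AHSP stood at 4.11 at 3.1 years, 2.90 to 5.30 in adults and 1.16 to 2.26 in the other animals.

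A candidate source of the adult-type signal at 471 days is RNA of another animal of the series. What the mean adult profile left of its deviations correlated across 659 genes at 0.350 with the deviations of the 6.5-year array, and at -0.06, -0.39, -0.02 and 0.03 with those of 7, 22.2, 26.1 and 3.1 years. The rule set in advance, a value above 0.3 and at least 0.2 above the next, was met. Adult deviations sum to about zero, so they depend on one another, and the negative value for 22.2 years is as large, which keeps this a hypothesis; genes are not independent replicates.

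Other splits of the same animals into groups of the same sizes were counted. For adults against immature animals, 1 of 100 splits, the real one, gave as many as 5652 genes, and the highest other gave 4014. These 100 were not all the possible splits, and they can show no result rarer than 1 of 100. The highest other split set the animals of 16, 20, 215 and 739 days against that of 471 days and the adults, which follows the structure of the samples. For adults against 3 to 4 years, 1 of 35 gave as many as 3366, with 1573 as the highest other. With 35 splits no result can be rarer than 1 of 35, so chance is made less likely but is not excluded. For 3 to 4 years against immature animals the real split gave 0 genes, so all 56 of 56 splits give at least as many by construction and the count says nothing about chance; the highest other, with the animals of 16, 20 and 215 days as a group, gave 156, a structure of the samples by age.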
